A study of Pimephales promelas with 32 samples.

How the data were processed

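Whole-body RNA of single fathead minnow larvae was analysed from 32 larvae in 3 groups. Per the labels, larvae described as 96 h post hatch in the treatment protocol were placed 10 to a beaker, in 5 beakers per treatment, each with 100 mL of solution. The age label gives 48 h post hatch for the same larvae, and the difference is not resolved here. All groups received 0.002% DMSO as vehicle, and larvae were kept at 25 °C. Per the labels' protocols, larvae were frozen after 48 h, RNA was extracted from each larva and libraries were made from 250 ng of total RNA with the Lexogen SENSE mRNA-Seq kit, which selects polyadenylated RNA. The description labels place 6 control, 5 bifenthrin and 5 copper sulfate larvae in sequencing lane 6 and 5, 5 and 6 larvae in lane 7.

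The authors deposited 1 table of raw counts, with whole numbers per gene model and larva and no normalization. The submitters' processing notes name bcl2fastq 2.19.1, STAR and limma, with no roles or parameters. The genome build, the annotation, the counting tool and its handling of strand and of reads that match several genes are not given in the sources used here. Each column was assigned to a larva by its description label, and 0 columns were left without a larva. Besides model numbers, the table lists protein accessions or enzyme class numbers, and 4139 models have neither. A reference table of gene symbols was searched, but 0 of the 26150 model numbers matched it. The gene lists and the rule for named genes that had been fixed before the data were examined both required symbols or product names, and none of the lists could be applied. In their place, the model with the smallest p in each direction and for each chemical is given, among genes with a mean count of at least 50. That ranking was fixed in advance, and the limit of 4 models was set later. The gene models were also grouped by shared annotation entries, a choice made after the data were seen.

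Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which kept 21174 genes with 99.9% of all counts and left out 4976. Libraries were scaled by TMM, and all 32 larvae were fitted together with group and lane as terms. Contrasts were tested with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were counted as called. This test returns no standard error. The SE of each log2 fold change was derived as its absolute value divided by the square root of F. The common biological coefficient of variation was 0.226. TMM factors averaged 1.03 in controls, 0.985 in bifenthrin larvae and 0.984 in copper sulfate larvae, and both treated groups differed from controls (permutation p = 0.00865 and p = 0.0183, 2-sided). Lane was significant for 0 genes in the edgeR test, with 2516 genes at an unadjusted p under 0.05. A lane-by-treatment interaction was called for 0 genes, with 637 at an unadjusted p under 0.05; no other tool was run for either term. CPM values are TMM-scaled except in the classifiers, which used library totals alone, and log2 CPM used a prior count of 2. Permutation tests of single measures used 100000 resamples.

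The relation between the effects of the chemicals was set beside 20 simulations of unchanged groups against the same controls and 20 lane-balanced splits of the controls drawn at random, of which 18 were distinct. Classifiers were linear support vector machines (e1071 1.7.16, cost 1) on log2 CPM of the 100 genes with the smallest p from limma 3.58.1 in the training larvae, with selection repeated for each larva left out. Intervals for classified larvae are exact Clopper-Pearson intervals at 95% and cover counting error only. Gene groups were tested with camera (preset correlation 0.01 and estimated correlation) and fry.

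The tests were checked on simulated data. Counts for the 21174 genes were drawn from the real means, library sizes and dispersions, with 200 genes changed per chemical. For bifenthrin against control, 59.4% of genes changed by 1.5-fold, 82.7% of those changed 2-fold and 98.4% of those changed 4-fold were recovered, and 5.33% of calls were false. For copper sulfate against control the shares were 57.1%, 95.9% and 98.4%, with 6.11% false calls.

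Over all 496 pairs of larvae, counts differed by at least 9.87 times sampling noise (chi-square per degree of freedom), so no pair agreed within sampling noise. The alternatives, set before the data were examined, were DESeq2 1.42.0 and its size factors, limma-voom with and without sample weights or a presumed beaker term, other abundance filters, no lane term, single lanes, a replicate block, fits of only the 2 groups compared and leaving out each larva. For classifiers they were 20 or 500 genes, a random forest (randomForest 4.7.1.2), training on 1 lane and testing on the other, and leaving out larvae with the same replicate number. Alternatives added after seeing the data were 2 covariates for larva-to-larva structure, removal of the 100 most abundant genes, thinning of all libraries to the lowest total, the correlation of effects without each larva, and effects read against another subset of the controls than the one used for calling. Larvae count as replicates of their group. Per the labels, at least 2 larvae per beaker were used, but the beaker of each larva is not given, so p-values treat larvae as independent.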

Results

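RNA-seq was performed on whole single larvae of the fathead minnow (Pimephales promelas), a small North American freshwater fish that is widely used in toxicity testing. Larvae were kept for 48 h in water with the pyrethroid insecticide bifenthrin at 3.2 µg/L (10 larvae), with copper sulfate at 40 µg/L (11 larvae) or as controls (11 larvae). Pyrethroids act on voltage-gated sodium channels of nerve and muscle, whereas dissolved copper disturbs ion uptake at the gill and oxidative balance. The series asks how specific transcriptional classifiers are for chemicals that act in different ways. The count table held 26150 gene models, and 21174 of these passed the abundance filter. Total counts ranged from 10655113 to 17993699 per larva. The mean total was 14085246 ± 2600502 in controls (SD, n = 11), 13604284 ± 1560446 in bifenthrin larvae (SD, n = 10) and 14132989 ± 1613666 in copper sulfate larvae (SD, n = 11). Depth did not separate either chemical from controls in 2-sided permutation tests (p = 0.614 for bifenthrin and p = 0.959 for copper sulfate). The table identifies its genes by model numbers and protein accessions that are not paired with gene names in the sources used here, so genes are described as groups and 4 gene models are given by identifier.

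Bifenthrin larvae were first compared with controls, to measure the response to a neurotoxic insecticide. A total of 8096 genes, 38.2% of those tested, differed between the groups. Of these, 3820 genes were higher and 4276 were lower in bifenthrin larvae. Most differences were small, with a median absolute log2 fold change of 0.49 among the genes that differed. Changes of more than 2-fold were found for 561 higher and 610 lower genes, and changes of more than 4-fold for 96 higher and 42 lower genes. The gene model FMg005786 (protein accession A4JYN9) rose from 2.99 ± 0.75 CPM in controls (SD, n = 11) to 47.6 ± 14.9 CPM in bifenthrin larvae (SD, n = 10). Its log2 fold change was 3.98 ± 0.20 (SE, edgeR quasi-likelihood test, adjusted p = 4.8e-16). All 10 bifenthrin larvae, at 23.3 CPM or more, exceeded the highest control, at 3.77 CPM. The same model stood at 3.13 ± 0.98 CPM in copper sulfate larvae (SD, n = 11), with a log2 fold change against control of 0.06 ± 0.20 (SE, edgeR adjusted p = 0.919). The gene model FMg015439 (A3KMS0) fell from 25.1 ± 3.88 CPM in controls (SD, n = 11) to 5.08 ± 0.80 CPM in bifenthrin larvae (SD, n = 10). Its log2 fold change was -2.30 ± 0.13 (SE, edgeR adjusted p = 2.1e-15), and in copper sulfate larvae it was -0.39 ± 0.11 (SE, edgeR adjusted p = 0.0366).

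The response to bifenthrin reached across the range of transcript abundance. When tested genes were ranked by mean count and cut into 4 equal classes, 1373 genes were higher and 1160 were lower in the most abundant class (median 848 counts per larva), and 170 rose and 60 fell by more than 2-fold. In the least abundant class (median 26.7), 519 were higher and 659 were lower, and 164 rose and 245 fell by more than 2-fold. The genes that rose made up 20.9% of the normalised counts of control larvae and those that fell 19.4%. For 657 higher and 687 lower genes, the range of the 10 bifenthrin larvae did not overlap the range of the 11 controls, where chance gives 5.7e-04% of genes. The 10 most abundant genes took 10.8 ± 0.60% of counts in bifenthrin larvae (SD, n = 10) and 9.82 ± 0.95% in controls (SD, n = 11; permutation test, 2-sided, p = 0.0131). In either lane alone fewer genes were called, with 2620 higher and 2653 lower in lane 6 and 1945 higher and 2106 lower in lane 7. The labels do not assign larvae to beakers, and larvae that shared a beaker would make these p-values too small.

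**Figure D1:**
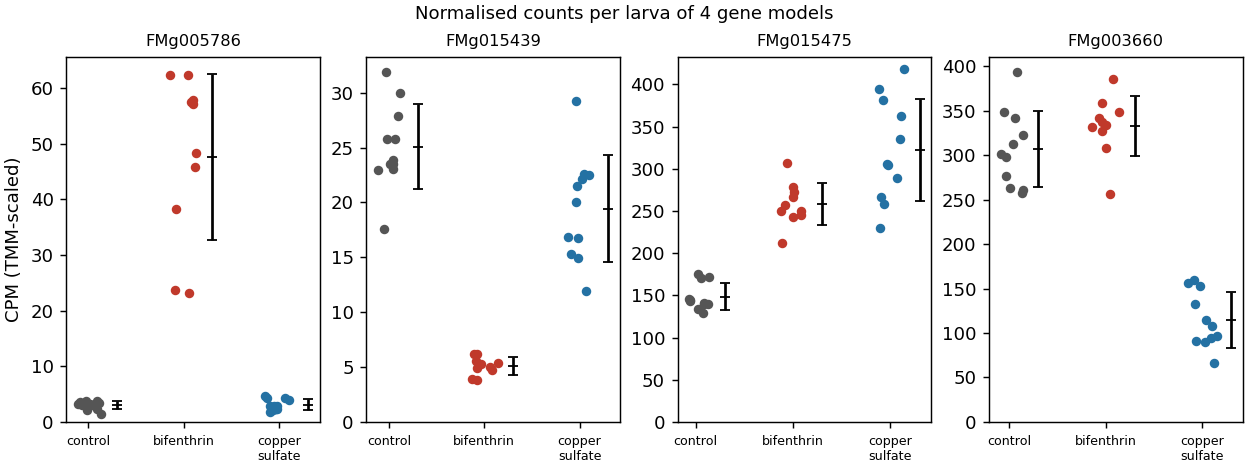
Normalised counts (CPM, linear axes from 0) of 4 gene models in each larva of the control, bifenthrin and copper sulfate groups, with the mean and SD beside the points. FMg005786 is at 23.3 CPM or more in bifenthrin larvae and at 4.61 CPM or less in the other larvae, and FMg003660 is at 159 CPM or less in copper sulfate larvae and at 256 CPM or more in the others.

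Copper sulfate larvae were compared with the same controls, to measure the response to a metal. The response was narrower. Each chemical was given at a single concentration, so the size of its response cannot be separated from the strength of the dose. A total of 1181 genes, 5.58% of those tested, differed between the groups, with 759 higher and 422 lower. Changes of more than 2-fold were found for 80 higher and 48 lower genes, and the median absolute log2 fold change among the genes that differed was 0.50. In the most abundant of the 4 classes 413 genes were higher and 103 were lower, whereas in the least abundant class 74 were higher and 66 were lower. The gene model FMg003660 (Q5U3P2) fell from 307 ± 42.7 CPM in controls (SD, n = 11) to 115 ± 31.3 CPM in copper sulfate larvae (SD, n = 11). Its log2 fold change was -1.43 ± 0.12 (SE, edgeR adjusted p = 8.3e-10), and all 11 copper sulfate larvae lay below the lowest control. In bifenthrin larvae the same model stood at 333 ± 33.7 CPM (SD, n = 10), with a log2 fold change of 0.11 ± 0.12 (SE, edgeR adjusted p = 0.476). The gene model FMg015475 (Q6IQM2) rose from 149 ± 16.1 CPM in controls (SD, n = 11) to 322 ± 60.9 CPM in copper sulfate larvae (SD, n = 11). Its log2 fold change was 1.11 ± 0.09 (SE, edgeR adjusted p = 5.7e-10). This model also rose in bifenthrin larvae, by 0.79 ± 0.09 on the log2 scale (SE, edgeR adjusted p = 8.8e-09).

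For 42 higher and 4 lower genes the ranges of the 11 copper sulfate and 11 control larvae did not overlap, where chance gives 2.8e-04% of genes. The number of lower genes depended on single larvae, with 259 called without copper sulfate replicate 4 and 275 without control replicate 7. In lane 6 alone 303 genes were higher and 78 lower, in lane 7 alone 82 were higher and 10 lower, and limma-voom with sample quality weights called 662 lower genes.

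The chemicals were then compared directly, which tests the difference between their effects. Here 6768 genes differed, with 3147 higher and 3621 lower in bifenthrin than in copper sulfate larvae, and 445 of the higher and 359 of the lower genes differed by more than 2-fold. FMg005786 was higher in bifenthrin larvae by 3.92 ± 0.19 on the log2 scale (SE, edgeR adjusted p = 8.8e-16), and FMg003660, which fell with copper sulfate, was higher by 1.54 ± 0.12 (SE, edgeR adjusted p = 1.1e-11). FMg015475, which rose with both chemicals, was lower in bifenthrin larvae by a log2 difference of -0.32 ± 0.09 (SE, edgeR adjusted p = 0.0055). Of the 437 genes called for copper sulfate and not for bifenthrin, 311 also passed the test of the difference between the chemicals. Of the 7352 genes called for bifenthrin and not for copper sulfate, 5081 did so. In lane 6 alone 1444 genes were higher and 1193 lower, and in lane 7 alone 1824 were higher and 1940 lower. An omnibus test of the 3 groups called 8466 genes.

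Both chemicals moved a set of genes in the same direction. Among genes called in both comparisons, 425 were higher and 271 were lower with both chemicals, and 48 moved in opposite directions. Lists of these sizes drawn independently would share 137 higher and 85.2 lower genes. This baseline, here and below, is not matched for abundance. In the most abundant of the 4 classes 47.8% of genes were called for bifenthrin and 9.75% for copper sulfate. In the least abundant class the shares were 22.3% and 2.64%. When bifenthrin and copper sulfate larvae were compared with separate subsets of the controls, the overlap was 205 higher and 79.7 lower genes on average over 20 random splits of the controls (18 distinct, 2 of them drawn 2 times), or 3.33 and 2.86 times that of independent lists of the same sizes. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated with r = 0.509. Simulated groups without any effect gave a mean r of 0.489 against the same controls, with a range of 0.468 to 0.511 that includes the observed value. The covariance was 0.0754 against a simulated 0.0176, a difference of 0.0578, and with split controls it was 0.0574 and r was 0.335. The genes that rose in copper sulfate larvae had a median log2 fold change of 0.50 there and 0.32 in bifenthrin larvae. The genes that fell in copper sulfate larvae had medians of -0.51 there and -0.55 in bifenthrin larvae. The genes that rose in bifenthrin larvae had a median of 0.10 in copper sulfate larvae and 0.48 in bifenthrin larvae, and those that fell had medians of -0.14 and -0.50. Because shared controls pull such medians the same way, genes were also called against one subset of the controls and read for the other chemical against the other subset, a check added after the data were seen. Averaged over the 20 splits drawn, genes that rose with copper sulfate then had a median of 0.31 in bifenthrin larvae (0.60 in copper sulfate larvae) and genes that fell a median of -0.36 (-0.64). Genes that rose with bifenthrin had a median of 0.09 in copper sulfate larvae (0.56 in bifenthrin larvae) and genes that fell a median of -0.12 (-0.56). Values for the chemical in which genes were called are raised in size by that choice of genes, and the difference between the chemicals in these medians was not tested.

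**Figure D2:**
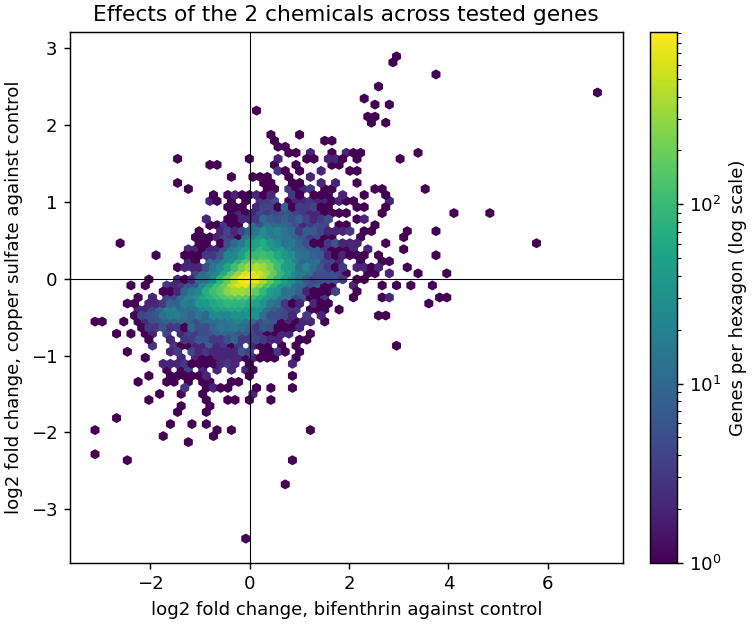
Density of the 21174 tested genes by their log2 fold change in bifenthrin (horizontal axis) and copper sulfate larvae (vertical axis) against the same controls, with colour giving genes per hexagon on a log scale. The cloud rises to the right (r = 0.509, where unchanged groups that share controls give 0.489) and extends farther along the bifenthrin axis.

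Whole transcriptomes gave the same order of effect sizes at the concentrations used. The root mean square log2 distance to the control centroid was 0.628 ± 0.047 in bifenthrin larvae (SD, n = 10) and 0.454 ± 0.036 among controls (SD, n = 11). No bifenthrin larva, at 0.552 or more, lay within the range of controls, whose highest value was 0.551, and the difference had a permutation p of 1e-05 (2-sided), the smallest that 100000 resamples can give. Copper sulfate larvae lay at 0.489 ± 0.046 (SD, n = 11), which was not separated from controls (permutation test, 2-sided, p = 0.055). Bifenthrin larvae differed less from one another than controls did, with a distance to their own centroid of 0.421 ± 0.024 (SD, n = 10; permutation p = 0.0129). For copper sulfate larvae this distance was 0.439 ± 0.066 (SD, n = 11; permutation p = 0.518). The first principal component of log2 CPM, with 21.8% of the variance, separated bifenthrin larvae from the others, whereas the second, with 9.79%, spread larvae within each group.

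**Figure D3:**
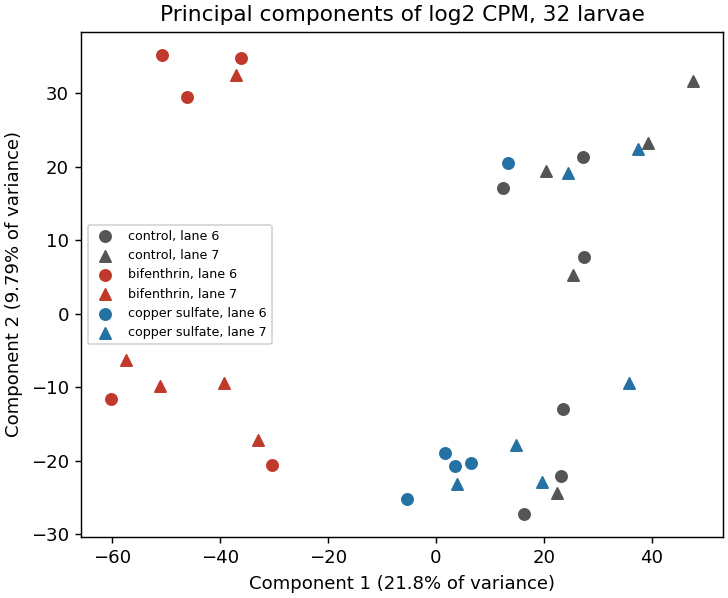
Principal components of log2 CPM in 32 larvae, with colour for the group and marker shape for the sequencing lane. Bifenthrin larvae lie at -30.3 or below on component 1 and the other larvae at -5.30 or above, and component 2 spreads the larvae of every group.

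Classifiers were trained to assign single larvae, which addresses the specificity question of the series. A linear support vector machine on 100 genes, tested on larvae left out of gene selection and training, assigned 21 of 21 bifenthrin and control larvae correctly (95% exact binomial interval 83.9 to 100%). It also assigned 22 of 22 copper sulfate and control larvae correctly (84.6 to 100%). With permuted labels the highest numbers correct were 18 and 19, and p was 0.01 in both cases, the smallest that 99 permutations can give. With 3 groups, 31 of 32 larvae were correct, and copper sulfate replicate 7 was called bifenthrin. The highest permuted number was 16 (p = 0.01). With 20 genes the number correct over 3 groups fell to 19 of 32. Because the beaker of each larva is not given, larvae of the same beaker may have stayed in training when a larva was left out. The numbers correct, intervals and p-values are therefore not for independent beakers.

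Each classifier was then applied to larvae of the chemical it had not seen. The classifier trained on bifenthrin and control larvae called 0 of 11 copper sulfate larvae treated, which allows a share of up to 28.5% (95% exact binomial interval). This number was 0 in all 5 alternative settings. Copper sulfate larvae had scores of -0.80 ± 0.31 (SD, n = 11) against -1.22 ± 0.22 in controls (SD, n = 11) and 1.17 ± 0.31 in bifenthrin larvae (SD, n = 10). The classifier trained on copper sulfate and control larvae called 10 of 10 bifenthrin larvae treated (69.2 to 100%). Bifenthrin larvae had scores of 0.42 ± 0.23 (SD, n = 10), between the -1.04 ± 0.27 of controls (SD, n = 11) and the 1.02 ± 0.44 of copper sulfate larvae (SD, n = 11). The result depended on the number of genes and the method: 1 of 10 bifenthrin larvae was called treated with 20 genes, 5 with a random forest and 10 with 500 genes. Classifier values were not TMM-scaled, so a composition difference shared by the treated groups may have entered these calls, which was not tested. With a single concentration per chemical, the difference between the classifiers cannot be separated from the strength of the doses.

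**Figure D4:**
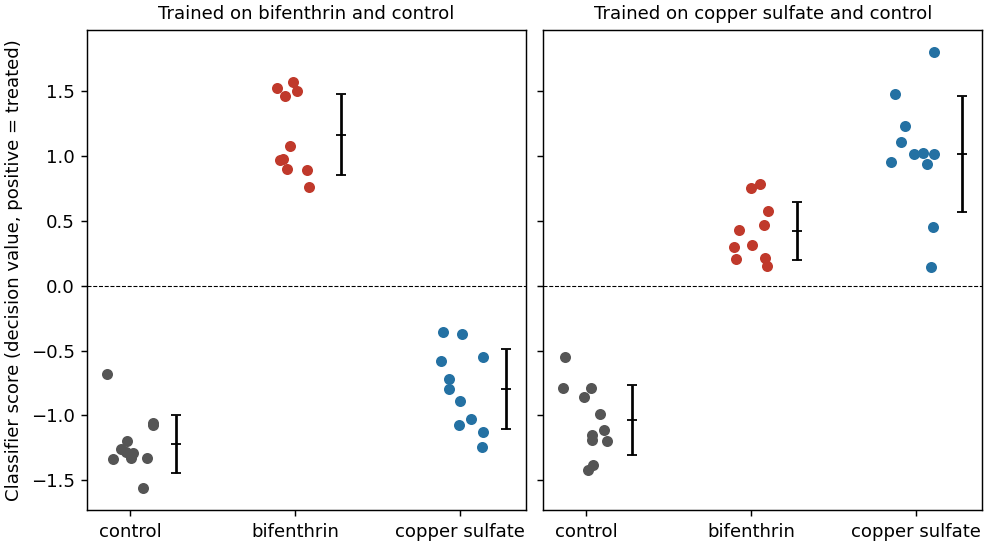
Classifier score (decision value, positive for treated) of each larva for classifiers trained on bifenthrin and control larvae (left) or copper sulfate and control larvae (right), with mean and SD beside the points; larvae of the training groups were left out when scored. Copper sulfate larvae score -0.36 or lower on the left, and bifenthrin larvae score 0.15 or higher on the right.

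Gene models that carry the same annotation entry in the deposited table were examined as groups, which were chosen after the data were seen. Of the 14 tested models annotated with the enzyme class of ribonuclease H, which cleaves RNA paired with DNA, 4 were higher and 0 lower in bifenthrin larvae, both over all genes tested and adjusted over the list alone. In copper sulfate larvae 1 was higher and 0 lower. Over all tested genes 38.2% were called for bifenthrin and 5.58% for copper sulfate. The counts of called members therefore do not by themselves set this or the following groups apart from other genes. This group reached an adjusted p of 0.094 for bifenthrin with camera (preset correlation), and adjusted p = 0.982 with an estimated correlation. A self-contained test (fry), which does not compare the group with other genes, gave an adjusted p of 0.0084. The 15 tested models of another entry (A5PF24), whose function the table does not state, gave the same count for bifenthrin, with 4 higher and 0 lower both over all genes tested and adjusted over the list alone, and 0 were called in copper sulfate larvae. Its adjusted p for bifenthrin was 0.094 with camera, 0.982 with an estimated correlation and 0.0084 with fry, and it also passed fry for bifenthrin against copper sulfate (adjusted p = 0.0386; 4 higher and 0 lower, 2 and 0 adjusted over the list alone). Of the 17 tested models annotated as aspartic endopeptidases, proteases with aspartate in the active site, 1 was higher and 0 lower in bifenthrin larvae, and 0 were called adjusted over the list alone. In copper sulfate larvae 1 was higher and 1 lower by either adjustment. The largest group from a single entry held 57 tested models, of which 4 were higher and 3 lower in bifenthrin larvae and 0 were called in copper sulfate larvae. Adjusted over the list alone, 0 of these 57 models were called for either chemical. None of the 48 tests (16 groups, 3 comparisons) passed an adjusted p of 0.05 with camera, with either correlation, and 3 passed with fry. The lanes differed with camera (preset correlation): for bifenthrin against control the adjusted p was 0.506 in lane 6 and 0.0036 in lane 7 for ribonuclease H, and 0.889 and 0.0036 for A5PF24, and between the chemicals it was 0.963 and 0.0067 for A5PF24. For copper sulfate against control ribonuclease H had 0.0233 in lane 6 and 0.131 in lane 7, and fry was not run by lane. Models of one entry may share reads, so counts of single members are uncertain.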

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

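Each count of called genes was recomputed under 16 other settings, 4 of them (the covariates, removal of the 100 most abundant genes and thinning) chosen after the data were seen, and without each of the 32 larvae in turn. For bifenthrin against control, 15 of 16 settings gave between 2620 and 4140 higher genes and 14 of 16 gave between 3763 and 4473 lower genes; leaving out single larvae gave 3545 to 4029 higher and 3913 to 4417 lower. For copper sulfate against control, 14 settings gave 537 to 919 higher genes and 12 gave 344 to 627 lower genes; leaving out single larvae gave 638 to 873 higher and 259 to 505 lower, the lowest without copper sulfate replicate 4, with 275 without control replicate 7. For bifenthrin against copper sulfate, 14 settings gave 2859 to 3412 higher and 14 gave 3210 to 3875 lower genes; leaving out single larvae gave 2878 to 3324 and 3288 to 3722. Single lanes, with fewer larvae, lowered the counts. Lane 6 alone gave 2653 lower genes for bifenthrin, 303 higher and 78 lower for copper sulfate, and 1444 higher and 1193 lower between the chemicals. Lane 7 alone gave 1945 higher and 2106 lower, 82 higher and 10 lower, and 1824 higher and 1940 lower. Limma-voom with sample weights called 662 lower genes for copper sulfate, of which 384 were among the 422; the cause was not tested. The 4 gene models given by identifier passed the threshold in the same direction in all 192 refits, each in the comparison for which it was picked. These models were picked for the smallest p in the same larvae, so passing was nearly fixed by the choice. Their calls in other comparisons were not checked in this way.

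Replicate numbers did not pair larvae: of 30 same-numbered pairs 4 correlated above 0.1 (range -0.28 to 0.14), and 0 of 32 larvae matched their own number best. A replicate block over the 10 numbers shared by the groups gave 190 lower genes for copper sulfate, and 537 higher genes; for bifenthrin it gave 3556 higher and 3918 lower, and between the chemicals 2859 higher and 3239 lower. The correlation of the effects was 0.496 without the lane term, 0.335 with split controls and 0.479 to 0.532 without single larvae. With 20 genes, 19 of 32 larvae were correct over 3 groups and 1 of 10 bifenthrin larvae was called treated by the copper sulfate classifier; with 500 genes 32 of 32 were correct, and a random forest called 5 of 10 treated; the causes were not tested. Of 48 tests of gene groups, 0 passed the threshold with a preset or estimated correlation, 3 with fry, 1 in lane 6 alone and 3 in lane 7 alone. A presumed beaker, from replicate numbers in runs of 3, had a correlation of 0.014 between its larvae. In simulations at these depths, 3 of 22 genes changed 1.5-fold between bifenthrin and control were recovered in the least abundant of 4 equal classes. In the most abundant class 12 of 13 were recovered. The simulated comparison called 169 genes, against 8096 in the real one, and the p cutoff of the adjustment depends on how many genes change. The simulation therefore cannot decide how many small changes of rare transcripts were detectable in the real comparison. In the data, 22.3% and 47.8% of genes were called for bifenthrin in the least and most abundant classes, and the cause was not tested.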

Other observations

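The split of the controls had been planned, but the way it is weighed here was chosen after the data were seen, as were the other tests in this part. The exception is the count of neighbouring genes, whose prediction was written before its result. Gene models that share an annotation entry moved together. Among 2174 pairs of models with the same entry and without consecutive numbers, taken from entries of 2 to 4 tested models, log2 fold changes correlated across pairs with r = 0.396 for bifenthrin and r = 0.269 for copper sulfate, against highest values of 0.0728 and 0.0580 in 999 permutations (p = 0.001, the smallest they can give). Pairs are not independent replicates. Where both models were called, 82.2% of 331 pairs changed in the same direction for bifenthrin, as did 100% of 32 pairs for copper sulfate. For the 304 pairs with consecutive numbers, r was 0.644 and 0.600. Chance pairing is excluded by these values. Shared regulation of gene copies and reads shared between near-identical copies may both contribute, and neither was tested. Among genes with a mean count of at least 50, 45.0% of 12638 models with an entry of their own were called for bifenthrin, and 20.95% of 210 models whose entry was shared by 5 or more. The median mean count was 285 in the first class and 122 in the second, so depth may account for part of this difference, which was not tested. For copper sulfate the shares called were 6.51% of models with an entry of their own, 8.24% of 461 models whose entry was shared by 3 to 4, and 4.76% of those shared by 5 or more, in no order of entry size.

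Larvae also differed from one another within every group. After removal of group and lane, the first principal component held 13.6% of the remaining variance, and 339 genes followed it with an absolute r over 0.7, of which 205 rose with it. In the bifenthrin group 4 larvae lay at -23.8 or below and 6 at 16.9 or above, with none between. The component was below zero in 6 of 11 controls and 4 of 11 copper sulfate larvae, and ranged from -37.2 to 31.2 and from -33.4 to 22.3 in these groups. With libraries thinned to the lowest total, 32 of 32 larvae kept the sign of their value, which argues against depth as the whole cause. Without the 100 most abundant genes 32 of 32 did as well. Nearly all genes were kept in that step, so it shows only that the component did not rest on those 100. The component also followed library composition, in 6 relations computed within the control and copper sulfate groups. In 11 controls it correlated with the share of counts in the 10 most abundant genes (r = -0.88, permutation p = 0.00048, adjusted 0.00144; rho = -0.95, permutation p = 6e-05, adjusted 0.00036; r = -0.91 without the 2 farthest larvae, r = -0.86 and rho = -0.89 in the 6 of lane 6, exact permutation p = 0.0125 and 0.0333) and with the TMM factor (r = 0.92, permutation p = 3e-05, adjusted 0.00018; rho = 0.88, permutation p = 0.00088, adjusted 0.00264; r = 0.87 without the 2 farthest, r = 0.80 and rho = 0.77 in lane 6, exact permutation p = 0.0486 and 0.103). In 11 copper sulfate larvae r for the share was -0.60 (permutation p = 0.0492, adjusted 0.0838) and rho -0.72 (permutation p = 0.0156, adjusted 0.0312), with r = -0.80 without the 2 farthest, and in the 6 of lane 7 r was -0.69 and rho -0.60 (exact permutation p = 0.14 and 0.242). For the total count r was -0.58 in controls (permutation p = 0.0622, adjusted 0.0838; rho = -0.56, permutation p = 0.0756, adjusted 0.113; r = -0.39 without the 2 farthest, r = -0.49 and rho = -0.49 in lane 6, exact permutation p = 0.336 and 0.356) and -0.57 in copper sulfate larvae (permutation p = 0.0698, adjusted 0.0838; rho = -0.42, permutation p = 0.206, adjusted 0.206; r = -0.59 without the 2 farthest), where it was stronger than the share in lane 7 (r = -0.89 and rho = -0.77, exact permutation p = 0.0347 and 0.103). For the TMM factor in copper sulfate larvae r was 0.39 (permutation p = 0.247, adjusted 0.247; rho = 0.42, permutation p = 0.204, adjusted 0.206; r = 0.53 without the 2 farthest, r = 0.18 and rho = 0.03 in lane 7, exact permutation p = 0.807 and 1). The within-lane p-values are not adjusted, and none was computed in the other lane of each group, whose 5 larvae are under the minimum of 6 set for a correlation. In the bifenthrin group, whose larvae lie in separate clusters so that no r is given, the share was 11.1 to 11.4% in the 4 larvae below zero and 9.79 to 11.2% in the other 6. RNA or library composition therefore stays open, as cause or consequence, and a part for the total count is not excluded. A candidate explanation is inherited differences between families of larvae. Among the 339 genes, 14 pairs of consecutively numbered genes shared no entry, against 2 to 8 in components 2 to 6 and at most 11 in 999 random draws. Genes without any entry count in such pairs and were not counted apart. They made up 15.6% of the 339 genes and 8.27% of tested genes. The labels give no parents, the numbers are not stated to follow the genome, and sex, stage and beaker stay open.

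The 8096 genes called for bifenthrin, against at most 1709 in 99 other groupings of the same larvae, and the 1181 called for copper sulfate, against at most 534, exceeded every other grouping, so 1 of 100 splits, the real one, reached as many in each case. The same held for the 6768 genes between the chemicals, where the highest other grouping gave 4015. Technical causes of the bifenthrin count were weighed: 8056 genes were called without the 100 most abundant genes and 7820 after thinning. The count therefore did not rest on those 100 genes or on unequal totals. Neither result could have differed much, because TMM scaling already limits the pull of a few genes and depth did not separate the groups. A score of the 339 genes, computed without removing the groups, was -0.19 ± 0.78 in controls (SD, n = 11) and 0.19 ± 0.81 in bifenthrin larvae (SD, n = 10; permutation p = 0.279). With this score as a covariate 3830 higher and 4266 lower genes were called, by coincidence again 8096 in all. This argues against an unequal mix of larval backgrounds along the first residual component. Backgrounds that differ along other components could not be tested by this score. An effect of bifenthrin on the larvae remains as a hypothesis. Differences between beakers, tested only through a presumed beaker term, and in the share of tissues in whole larvae stay open.

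The overlap of the chemicals may reflect a response common to both. With separate subsets of the controls, each split was run with the subsets assigned both ways and the overlaps were averaged. This average was at least 2.47 times that of independent lists, not matched for abundance, in each direction over the 18 distinct splits. It argues against shared control larvae as the whole cause. With the background score as a covariate 477 genes were higher and 335 lower with both chemicals. The covariance of the effects was 0.0722 with the score and 0.0754 without it, which argues against an unequal mix of backgrounds along the first residual component as the whole cause. The highest simulated value was 0.0189, but the simulations hold no differences in background and cannot decide this. Backgrounds along other components were not tested. A common response to stress, or slower growth in both groups, stays open because the genes carry no names here, and handling that differed between control and treated beakers was not tested.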
